A study of Homo sapiens with 3 samples.

How the data were processed

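Ribosome footprints of HEK293 cells were measured in 3 libraries, 1 each for the footprinting conditions labelled low, medium and high. Per the labels' protocols, cells were lysed with detergent, lysates were digested with RNase I, ribosomes were pelleted through a sucrose cushion, fragments were chosen by size on a gel, and libraries were made by linker ligation, reverse transcription and circularization. The submitters' processing notes name CASAVA 1.8.1, Bowtie 0.12.7, TopHat 1.2.0 and the genome build hg19, without their roles. How the authors assigned reads to transcripts, isoforms or frames, the read end and offset used for the frame, and any treatment of duplicates or of reads with several matches are not given in the sources used here.

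For each library the authors deposited a table of read counts by fragment length (25 to 34 nt, per the file headers) and frame, with 3 frames in unnamed columns. The same deposited table gives each length's fraction of all reads and each frame's fraction of the reads of that length, and both were checked to lie within 0.0001 of the counts divided by their totals. A second deposited table gives a whole-number count of reads for each of 62378 transcript identifiers, with a length whose unit is not given. Identifiers and lengths were identical in the 3 libraries. No column of any other sample was used.

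The totals of the transcript tables were 4713437 counts in the low library, 8312451 in the medium library and 8027049 in the high library, or 2.76, 2.79 and 2.74 times the totals of the frame tables. The frame tables may hold only part of the reads, so these ratios do not show how often a read was counted. Of the 17134 rows examined for high over low, 3718 equalled another row in listed length and in the counts of all 3 libraries, against 12 after the lengths were shuffled among the rows, as rows that count the same reads would. Rows were therefore not taken as independent. Of the 62378 rows, 14197 had no read in any library and 42298 had a read in all 3. Rows with the same listed length and the same counts in all 3 libraries, taken once, number 42769. Of the 48181 rows with a read in any library, 41436 remain when taken once. Many of the merged rows thus had no read and only shared a listed length. A count of 0 allows up to 3 reads, or 0.636, 0.361 and 0.374 RPM (reads per 1000000 reads of the library's transcript table) in the low, medium and high libraries. Sequenced reads without molecular identifiers are not independent molecules, so the floors and the intervals of shares, means and ratios cover counting error only.

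Shares of reads are given with exact Clopper-Pearson 95% intervals. Rows with a mean of at least 64 reads per library in the 2 libraries compared were examined. Ratios of RPM have exact binomial 95% intervals; a row was counted as higher or lower where the ratio was at least 1.5-fold and the interval excluded 1. This is a rule of size for 2 libraries and not a test of a condition. Correlations and SDs used log2 values with a pseudocount of 0.5 reads. The spread from counting alone came from 100 Poisson simulations with the same expected share in both libraries. These simulations treat rows as independent. The rule was tested on simulated data for each pair of libraries: in the simulation of high over low, over 17134 rows with 50 rows changed by each size, the rule called 96% of the rows changed 2-fold, 96% of those changed 1.75-fold, 52% of those changed 1.5-fold, which lie at the threshold itself, and 0.561% of the unchanged rows. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. TMM factors, used for an alternative scaling, came from edgeR 4.0.16 in R 4.3.3.

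The comparisons, the rules and most alternatives were fixed before the data were examined. The rule for named rows was to rank them, for high over low, by the bound of the 95% interval nearest to no change and to name the 10 highest and 10 lowest, with 5 of each for the other pairs, the 10 most abundant rows of each library and up to 2 of each direction in each gene list. Because the files do not pair the identifiers with gene names, only the first 2 of each direction for high over low are named. Of the 62378 identifiers, 0 occur in the gene table used here, and 1 occurs there under another version number and was not used. That gene table holds names of this style only 8 times, so it could hardly pair them and does not show that they lack gene names. For this reason 32 lists of genes were not analysed here. Coordinates were not used here. Alternatives were other scalings, read minimums of a mean of 16 or 256 reads per library, a 2-fold difference, a 99% interval, other sets of fragment lengths and, added after the data were seen, identical rows taken once and scaling to the totals of the frame tables.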

Results

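Ribosome profiling sequences the short mRNA fragments that a ribosome shields from nuclease, so that fragment length reports the extent of protection and fragment position reports the codon being read. The libraries came from HEK293, an established human embryonic kidney cell line, and were made from lysates digested with RNase I, a nuclease that cuts single-stranded RNA. The series compared 3 footprinting conditions, labelled low, medium and high, and the labels do not say which quantity was set low or high. Each condition held 1 library, so no difference between conditions has a replicate check and no test between conditions could be made. Every comparison below is between libraries, and its intervals cover counting error only. The tables of read length and reading frame held 1704888 reads in the low library, 2981542 in the medium library and 2930859 in the high library. The transcript tables listed 62378 transcript identifiers, of which 44168 had at least 1 read in the low library, 45912 in the medium library and 45425 in the high library.

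Footprints were shortest and most narrowly distributed in the low library. Their mean length was 27.4 nt in the low library (SD over reads 1.18 nt), 27.9 nt in the medium library (SD 1.31 nt) and 27.8 nt in the high library (SD 1.41 nt). The means did not follow the order of the condition labels, since the medium library had the longest footprints. Fragments of 27 nt made up 32.7% of the low library (exact Clopper-Pearson 95% interval 32.7 to 32.8%), 21.6% of the medium library (21.5 to 21.6%) and 22.2% of the high library (22.1 to 22.2%). The share of 28-nt fragments differed less, at 32.5%, 32.9% and 29.02% in the low, medium and high libraries. Fragments of 29 to 34 nt were 15.2% of the low library, 31.5% of the medium library and 29.8% of the high library. Those of 30 nt or more were 2.59%, 8.22% and 9.46% in the same order. At the short end, fragments of 25 and 26 nt were 19.5% of the low library and 19.1% of the high library, and 13.9% of the medium library. The high library therefore held more long fragments than the low library and nearly the same share of the shortest ones. The tables hold lengths from 25 to 34 nt, and fragments outside that window were not analysed here.

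**Figure D1:**
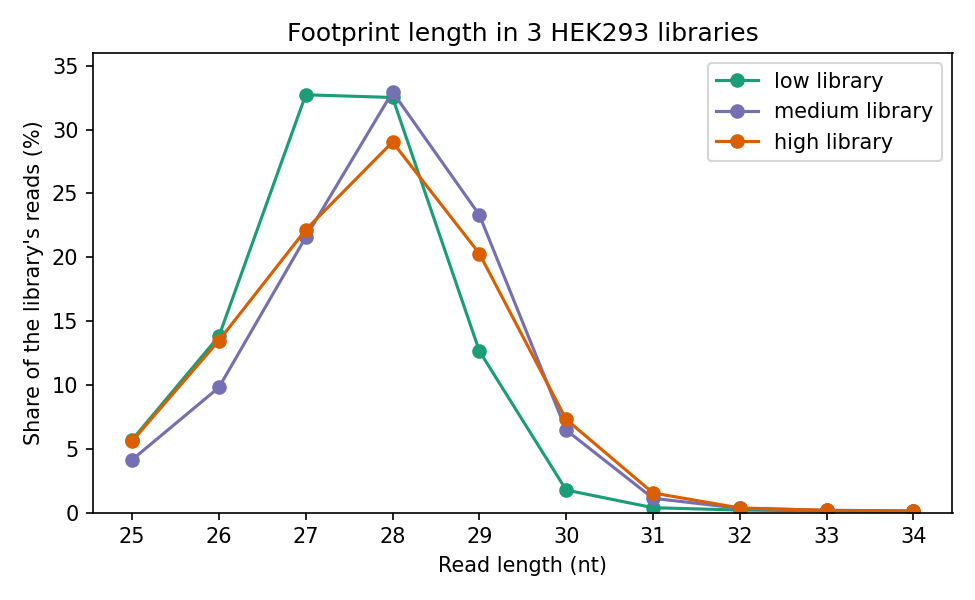
Share of each library's reads (y axis, %) at each read length (x axis, nt) in the low, medium and high libraries; each point is 1 library. The low library peaks at 27 nt with 32.7% of its reads, and the medium and high libraries peak at 28 nt with 32.9% and 29.02%.

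Fragments occupied the 3 reading frames unequally in all 3 libraries. Ribosomes advance by whole codons, so the fragments they protect favour particular frames. The frames are numbered 1 to 3 here in the order in which the tables list them, because the tables do not name them. Frame 2 held 48.7% of the reads of the low library, 44.8% of the medium library and 45.9% of the high library. Frame 1 held 37.0%, 40.5% and 36.5%, and frame 3 held 14.3%, 14.6% and 17.6%, in the same order. The exact 95% intervals of the 3 libraries did not overlap in any frame (frame 2: 48.6 to 48.8% in the low library, 44.8 to 44.9% in the medium library and 45.9 to 46.0% in the high library). The order of the libraries in frame 2 depended on the lengths taken: it was lowest in the low library with only 28 to 32 nt (34.98%, 40.4% and 44.3% in the low, medium and high libraries) and with each length given its mean share over the 3 libraries (43.6%, 46.7% and 47.3%).

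The frame that held most fragments depended on fragment length and, among lengths from 25 to 31 nt, differed between the libraries at 25, 26 and 28 nt. Fragments of 27 nt were most frequent in frame 2, with 74.97% in the low library (74.9 to 75.1%), 57.9% in the medium library (57.8 to 58.0%) and 46.2% in the high library (46.1 to 46.3%). Those of 29 nt were most frequent in frame 1, with 80.3% (80.1 to 80.4%), 71.6% (71.4 to 71.7%) and 57.6% (57.4 to 57.7%) in the low, medium and high libraries. At 28 nt the leading frame changed, from frame 1 with 51.6% in the low library to frame 2 with 60.6% in the medium library and 61.5% in the high library. Frame 2 held 45.0% of the 28-nt fragments of the low library. At 26 nt the low library had most fragments in frame 3 (43.2%), whereas the medium and high libraries had most in frame 2 (43.2% and 49.7%). At 25 nt the low library led in frame 1 with 41.0%, and the medium and high libraries led in frame 2 with 50.9% and 52.8%. Fragments of 30 nt led in frame 1 in all 3 libraries, with 54.5%, 63.4% and 60.8%. At 31 nt the high library held nearly equal shares in frame 1 (42.1%) and frame 3 (41.6%), and their intervals overlapped.

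**Figure D2:**
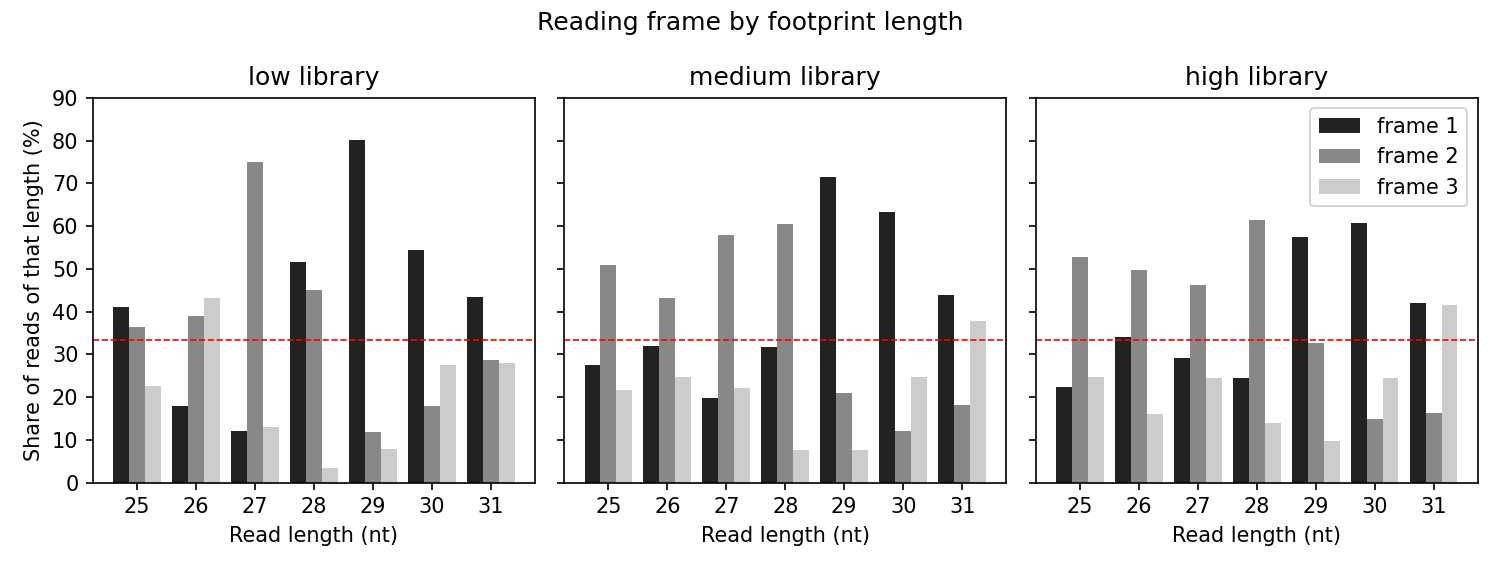
Share of the fragments of each length (y axis, %) in frames 1, 2 and 3 by read length (x axis, nt, 25 to 31) in the low, medium and high libraries; bars start at 0 and the dashed line marks equal shares. At 28 nt the tallest bar is frame 1 in the low library (51.6%) and frame 2 in the medium (60.6%) and high (61.5%) libraries.

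Taking at each length its own leading frame, 61.1% of the reads of the low library (61.0 to 61.1%), 60.3% of the medium library (60.3 to 60.4%) and 54.8% of the high library (54.7 to 54.8%) lay in the leading frame. The lower value of the high library did not hold at all lengths, and with only 28 to 32 nt the order of the low and high libraries turned, at 59.2% in the low library, 64.5% in the medium library and 59.4% in the high library. Of the 6 lengths with at least 10000 reads in every library, the leading-frame share was higher in the high library than in the low library at 4 (25, 26, 28 and 30 nt) and lower at 27 and 29 nt.

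The commonest kinds of fragment also differed. In the low library the most frequent combination was 27 nt in frame 2, with 24.5% of all reads, followed by 28 nt in frame 1 with 16.8%. In the medium library the most frequent was 28 nt in frame 2, with 19.97%, followed by 29 nt in frame 1 with 16.7%. The high library had the same leading pair as the medium library, at 17.9% and 11.7%. The 4 most frequent combinations together held 66.1% of the low library, 59.6% of the medium library and 46.9% of the high library.

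Footprint counts per transcript were closely related between the 3 libraries. Across the 17134 transcript rows with a mean of at least 64 reads per library in the high and low libraries, log2 RPM (reads per 1000000 reads of the library's transcript table) correlated with Pearson's r = 0.972 and Spearman's rho = 0.942. The medium and low libraries gave r = 0.983 and rho = 0.961 over 17331 rows, and the high and medium libraries gave r = 0.985 and rho = 0.969 over 19946 rows. These 3 correlations are across rows, which are not independent replicates, and some rows had identical counts. Poisson counting alone gave a mean simulated r of 0.9903, 0.9903 and 0.992 for the 3 pairs in the same order. The high and low libraries were the pair furthest apart. The log2 ratio of high over low had an SD of 0.30, against 0.18 from counting alone, which leaves 0.25 beyond counting, or a factor of 1.19. The SD beyond counting was 0.16 (a factor of 1.12) for medium over low and 0.16 (a factor of 1.11) for high over medium.

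Ratios of at least 1.5-fold were few. Between the high and low libraries, 676 rows were at least 1.5-fold higher and 336 at least 1.5-fold lower in the high library with an exact 95% interval that excluded no change, together 5.91% of the rows tested. Simulated Poisson counts without any change gave 94.2 such rows on average and 121 at most in 100 simulations. In every pair the interval excluded no change in each examined row at least 1.5-fold apart, so the ratio alone decided these counts. When the libraries were scaled to their upper quartiles instead of their totals, the split was 493 higher and 467 lower, so the excess of higher over lower rows depends on the scaling. Medium over low gave 284 higher and 130 lower rows (229 and 182 with upper-quartile scaling), and high over medium gave 177 higher and 185 lower rows (161 and 209 with upper-quartile scaling, 149 and 231 with scaling to the totals of the frame tables). Simulations without change gave at most 121 rows for medium over low and 101 for high over medium. Among the well-covered rows, with a mean of at least 256 reads per library, high over low gave 53 higher and 33 lower rows of 4903, whereas simulations without change gave 0. Medium over low gave 5 such rows of 4931 and high over medium gave 3 of 6330, with at most 1 in any simulation of either pair. Differences of 2-fold or more were found in 31 higher and 13 lower rows for high over low, in 10 and 3 rows for medium over low, and in 1 and 5 rows for high over medium.

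**Figure D3:**
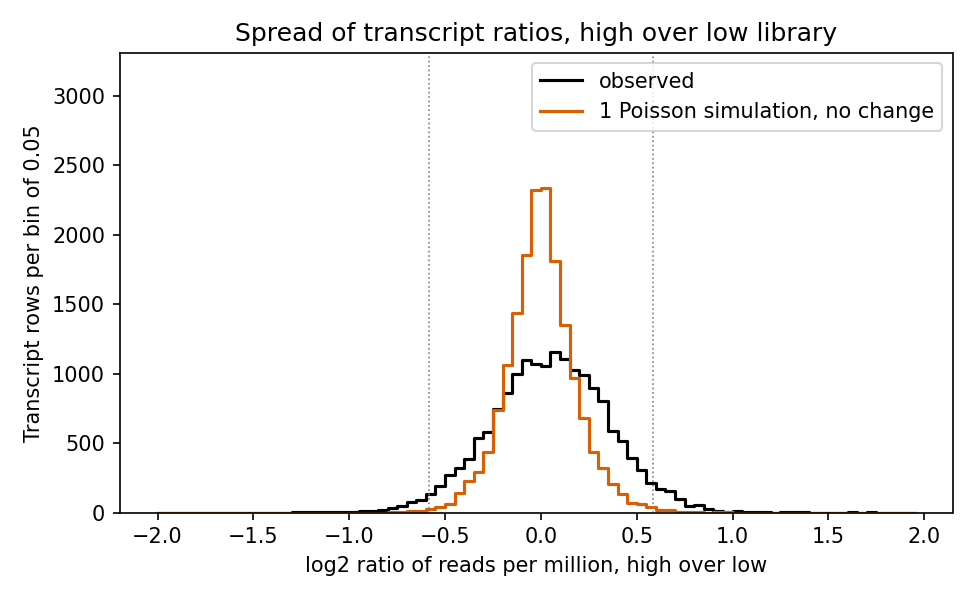
Number of transcript rows (y axis, per bin of 0.05) by log2 ratio of RPM in the high over the low library (x axis), for the data and for 1 Poisson simulation without change; dotted lines mark 1.5-fold. The observed distribution (SD 0.30) is wider than counting alone gives (SD 0.18).

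The files identify transcripts by UCSC-style identifiers and do not pair them with gene names. The gene table used here holds hardly any names of this style, and none of the identifiers matched it in full. Rows are therefore given by identifier without a gene name or position. Rows were ranked for high over low by the bound of the 95% interval nearest to no change, and not by the ratio itself. The first row above no change was uc004coy.2, with 1415 reads in the high library and 321 in the low library. Its abundance was 176 RPM in the high library (95% interval 167 to 186), 173 in the medium library (164 to 182) and 68.1 in the low library (60.9 to 76.0), a 2.59-fold ratio of high over low (2.29 to 2.93). The second was uc001cwi.1, at 20.1 RPM in the high library, 11.4 in the medium library and 5.94 in the low library, a 3.38-fold ratio (2.25 to 5.24) that rests on 28 reads in the low library. By the same ranking the first row below no change was uc001hsx.1, at 64.5 RPM in the high library, 97.9 in the medium library and 140 in the low library. Its ratio was 0.459 (0.409 to 0.516). The next was uc003zpo.2, at 14.0, 19.4 and 33.9 RPM in the high, medium and low libraries, a ratio of 0.411 (0.320 to 0.527).

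Ratios changed little with the length listed for each transcript. With the rows split into 5 groups of nearly equal size by listed length, the median high over low ratio was 1.02-fold in the shortest group (listed length 6 to 233) and 1.06-fold in the longest group (835 to 8778), and Spearman's rho of the ratio with length across rows was 0.053. It was 0.058 for medium over low and 0.014 for high over medium. With a mean of at least 256 reads per library it was 0.112 for high over low and 0.152 for medium over low. Short rows were more variable: the SD of the high over low log2 ratio beyond counting was 0.28 in the shortest group and 0.23 in the longest. Rows lower in the high library made up 3.45% of the shortest group and 1.34% of the longest, and rows higher in the high library made up 4.70% and 2.83%. The unit of the listed length is not given in the sources used here.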

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

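Identical rows taken once and scaling to the totals of the frame tables were chosen after seeing the data; the other alternatives were set before. Of the report's main values under the alternatives, 50 stayed within their interval or, for counts, within 1.5 times the main count, and 58 moved. For r, rho and SD this interval came from 200 random draws of the rows with replacement, which treat rows as independent. Some outcomes were fixed in advance: a modal length is a whole number outside the narrow interval of a mean, and a 2-fold difference or a higher read minimum can only lower a count. The causes of the other moves were not tested, except that fewer or more rows were examined under other read minimums. No paired analysis was possible because each condition is 1 library, and no library could be left out. All 10 lengths occur in the 3 libraries, so taking only shared lengths changed nothing. The alternatives with 1 row per gene symbol, on gene lists and their matching, and without ribosomal protein and histone genes were not run, because the files do not pair identifiers with gene names. Values are given for the low, medium and high libraries in this order. The modal length was 27, 28 and 28 nt, and with 26 to 34 nt the mean was 27.6, 28.01 and 27.9 nt. At the modal length, frame 2, there the leading frame, held 74.97%, 60.6% and 61.5%. With 28 to 32 nt, frame 2 held 34.98%, 40.4% and 44.3%, and the leading frame 59.2%, 64.5% and 59.4%. With each length at its mean share over the 3 libraries, frame 2 held 43.6%, 46.7% and 47.3%, and the leading frame 61.3%, 59.2% and 54.6%. The order of the low and high libraries thus turned for frame 2 under the last 2 settings and for the leading frame at 28 to 32 nt and not under common weights.

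For medium over low, high over medium and high over low in this order, a mean of at least 16 reads per library gave Pearson's r of 0.976, 0.980 and 0.968, SDs of the log2 ratio of 0.36, 0.34 and 0.41, 891, 673 and 1524 rows higher, and 652, 862 and 1217 lower. A mean of at least 256 reads gave r of 0.989, 0.9899 and 0.975, SDs of 0.16, 0.16 and 0.24, 3, 1 and 53 rows higher, and 2, 2 and 33 lower. Spearman's rho of the ratio with listed length was 0.0322 for medium over low and 0.0331 for high over low at 16 reads, and 0.152 and 0.112 at 256 reads. At least 2-fold, 10, 1 and 31 rows were higher and 3, 5 and 13 lower. With the other scalings, a 99% interval and identical rows taken once, each of these counts stayed within 1.5 times the main one. The 4 named rows kept their call under all 4 other scalings. These moved high over low by at most 0.045 log2, too little to undo a call of such extreme rows. In simulated data for high over low, over 17134 rows, the 1.5-fold rule called 96% of the rows changed 2-fold. Counting depth thus left few 2-fold changes out of the counts by the 1.5-fold rule. Recovery at the 2-fold threshold was not simulated, and rows with fewer reads than the minimum were not examined.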

Other observations

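The tests of the mix of read lengths, of counting noise and of trends with listed length and abundance were set before their results were seen. The tests of frameless reads, of a frame offset, of the read ends and of the covariance of ratios, and the counts of abundant short rows, were chosen only after the result was seen.

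With identical rows taken once and the rows split into 5 equal groups by abundance, the most abundant group (2985 rows, with at least 688 reads in the pair) held 25 rows at least 1.5-fold lower and 18 at least 1.5-fold higher in the high library than in the low library. Of the 25 lower rows, 14 were among the 672 of the 2985 rows that were also in the shortest of 5 groups by listed length (up to 233), where 5 rows were higher. Only rows equal in listed length and in all counts were merged, so some of the 14 may still count the same reads. Of the 586 abundant rows in the longest group, 0 were lower and 6 were higher. Under the 4 other scalings the lower rows numbered 27 to 38, of which 15 to 18 were in the shortest group and 0 in the longest, and the higher rows numbered 9 (upper quartiles) to 16. All 4 scalings lowered every ratio of high over low, so lower rows could not become fewer, nor higher rows more. Several of the 14 rows lay near the threshold, with ratios up to 0.667, so a shift the other way could remove some of them. In the least abundant group, 50 of 636 short rows were lower and 61 higher, and 13 of 552 long rows were lower and 38 higher.

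Read length and frame differed between the low and the high library. The mix of read lengths does not account for the larger leading-frame share of the low library: the gap was 6.30 percentage points as measured and 6.72 with each length given its mean share over the 3 libraries. Frameless reads, if they were the only change in the high library, would lower that share at every length. It was higher beyond the intervals at 4 of 6 lengths. At 25, 26 and 28 nt, among these 4, the leading frame itself differed between the low and the high library. Frameless reads added beside another change therefore stay open. A frame offset set per length, if it were the only difference, would only rename the frames of a length. The share differed beyond the intervals at 6 of 6 lengths (74.97% in the low and 46.2% in the high library at 27 nt), so an offset alone does not give these values. An offset beside another difference stays open. The phase shares of the read end from which the frame was not counted differed more than those of the listed frame (3.30 points, as 0.5 of the summed absolute differences) whichever end was used, by 26.5 points if the frame was counted from the 5′ end and by 7.47 if from the 3′ end, which is over 2 times as much, but that phase is calculated from frame and length together, and with common length weights the values were 7.04, 19.97 and 7.61, nearly equal under the 3′ assumption, so the end stays open. A biological difference between the conditions stays open, as does any other difference between libraries, since each condition is 1 library.

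The 1012 transcript rows at least 1.5-fold apart between the high and the low library are more than counting noise gave, which reached at most 121 rows in 100 simulations. A trend of the median ratio with listed length or with abundance is not the whole cause either. After the median ratio of each of 20 bins was removed, 996 rows were called for listed length, 842 of them among the original rows, and 986 for abundance, 826 of them among the original rows. In 5 groups the medians were only 1.02 to 1.06-fold by listed length and 1.02 to 1.05-fold by abundance. Their removal thus could not take away most calls at 1.5-fold. It also leaves the larger spread of short and of less abundant rows in place, so a trend in spread was not tested. No biological explanation was separated from a difference between libraries, because each condition is 1 library.

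The log2 ratios of medium over low and of high over medium varied together across rows more than counting gives. The first form of this test asked for a covariance above 0. It was met with a mean of at least 171 reads per library (0.00264 over 7075 distinct rows) but not with at least 42.7 (-0.0118 over 19919 rows), and the criterion was then changed to the difference from Poisson simulations, because the shared medium library makes the covariance negative with no effect at all. By the changed criterion the covariance lay above the simulated mean by 0.00804 (mean -0.00540, highest -0.00493) and by 0.00501 (mean -0.0168, highest -0.0159). This argues against independent variation of each library, for which the difference would be at or below 0. With the low or the high library in the middle, over the 19919 rows, the difference was -0.0356 and -0.0311. Both values must be negative once the one with the medium library in the middle is above 0, so they add nothing to it. The difference above 0 means that the variance beyond counting of high over low exceeded the sum of those of the other pairs. That is more than being the pair furthest apart, and it rests on the same ratios. A shift along the order low, medium, high, through the footprinting condition or another gradient between the libraries, may fit these values and was not tested further.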
